A study of Mus musculus with 6 samples.

How the data were processed

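RNA from intestinal crypts of 3 control and 3 knockout mouse samples was hybridized to an Illumina bead array, per the labels' protocols by biotin labelling and direct hybridization. The authors deposited 1 signal intensity per probe and array; the values show neither background subtraction nor scaling between arrays. They also deposited a detection p-value for each probe and array, per the file headers; its steps imply 936 negative control probes. The deposited value table holds log2 values of 15614 probes, those detected on at least 1 array. Its column medians are all 7.529, which goes with quantile normalization, and each column correlated with the log2 intensity of its own array (r from 0.9993 to 1) more than with any other array. The software and settings behind these tables are not given in the sources used here.

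Columns were matched to samples by the sample titles, and 0 columns were left unmapped. Groups came from the genotype labels. The titles carry the letters A to C for controls and D to F for knockouts, and replicates are numbered in that order within each group. No slide or scan date was given in the sources used here, so array batches were not tested. No pair of libraries was identical (0 pairs). No title letter recurs across the groups, and the replicate number did not pair the samples. The correlations of same-numbered deviations from the group means were -0.0852, -0.106 and 0.0379.

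Probe names came from the platform annotation given with the series, which can be old, with symbols updated through a mouse gene table (assembly GRCm38.p6) used for names only. Among the 15614 probes of the value table, 13211 had 1 gene symbol, 6 had several and 2397 had none; of the 12217 tested probes the numbers were 10524, 6 and 1687. No coordinates are printed, since the array's build is not given in the sources used here.

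In R 4.3.3 with limma 3.58.1, intensities were background-corrected and quantile-normalized with neqc (normexp with the negative-control mean and spread inferred from the detection p-values, offset 16) and put on a log2 scale. A probe was tested when its detection p was under 0.05 on at least 3 of 6 arrays. Knockout was compared with control by lmFit and eBayes on all 6 samples without covariates, two-sided, with Benjamini-Hochberg adjustment at 0.05. A gene was represented by its brightest tested probe. Where a probe was undetected on every array of a group, its fold change is given as a lower bound. Such a bound holds for the background-corrected values only and carries no error. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

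Before the data were examined, 38 gene lists were fixed, together with the joined Paneth list. They covered Paneth defensins and other Paneth genes, goblet, enteroendocrine, tuft, stem, enterocyte and secretory regulator genes, the cell cycle, polycomb, atypical protein kinase C partners and cytokines. They also covered antimicrobial, interferon, MHC class II, unfolded protein, cell death, Wnt, Notch, YAP, PPAR, cholesterol and xenobiotic genes. The rest marked T, B, myeloid, mast, stromal, endothelial, erythroid and pancreatic cells, proximal, distal and colonic segments, clock, immediate early and heat shock genes and the Y chromosome. The 32 lists with at least 5 tested genes were tested with camera (preset correlation 0.01) and adjusted over the lists; 14 were called with camera. With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and fry, a directional rotation test, called 1, with 6 at an unadjusted p under 0.05. The mean Paneth level was also tested by an exact two-sided permutation of the samples.

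The genes to name were set by a rule fixed beforehand: 10 genes of interest where a probe existed, the 12 largest changes on each side among called genes without overlap of the groups, up to 4 called members of each called list or else the 2 with the lowest p, and up to 2 members of the lists of other cell types and sample quality. Xist and the probes of the closing section that were left out of the test were chosen after their values were seen.

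The fit was tested on simulated data over the 12217 probes with normal noise at the mean and fitted spread of each probe, 100 probes changed 2-fold and 100 changed 4-fold. It recovered 64 of the 2-fold and 100 of the 4-fold changes, with 10 false calls. A list shifted by 0.5 on the log2 scale was called and 0 of the other lists were. The simulated noise was independent between probes, so this does not show how often lists of correlated genes are called without a shift.

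Alternatives fixed beforehand covered background correction, the authors' value table, the normalization, the detection filter, the eBayes settings, array weights, a fold threshold, the replicate block, set tests, probe choice, thresholds and leaving out each sample. After the data were seen, 2 were added for Y-linked signal: the knockout reduced to replicate 1, and a term for the 2 libraries that carry it. Explanations in the closing section were judged by rules written down first, some after the value had been seen. For several tests a condition was added or changed after the values were known. The sex test also had to exceed the spread of the control libraries, which turned the tuft cell verdict from excluded to undecided. Its written rule was also wrong to let 1 knockout library without Y-linked signal exclude sex, so more than 1 is now required and the verdicts on Paneth cell, cholesterol and proximal genes went from excluded to undecided. The distal ileum median had to exceed 2 standard errors, taken over its genes, which did the same for the segment. The rules for Lyz1 and for cross-hybridization were tightened because signal from other sources and shared signal among defensins leave these tests undecided, and the verdicts went from excluded to undecided.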

Results

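Gene expression was measured in isolated intestinal crypts of mice with an Illumina bead array, a chip on which each probe is read as the brightness of labelled RNA bound to beads. The crypts came from 3 mouse samples with loxP-flanked Prkci alleles and no recombinase, called control here, and from 3 samples in which the same alleles were combined with VilCre, called knockout here. Prkci encodes an atypical protein kinase C, and VilCre is a Cre recombinase driven by the villin promoter, which is active in the intestinal epithelium. The series record describes the samples as biological replicates. Between 11748 and 12626 probes, 25.9% to 27.9% of the array, were detected on each array at a detection p under 0.05, and 12217 probes entered the test. The number of arrays, 3 per group, limits the precision of every value below.

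The comparison asks how crypt gene expression differs when Prkci is deleted from the intestinal epithelium, with Paneth cells, the antimicrobial secretory cells at the crypt base, named in the title of the series. The targeted gene came first in the plan. Prkci was not analysed here, because no probe was assigned to it in the annotation used, so the deletion was not checked from the arrays. Ezh2, Atoh1, Mmp7 and Lgr5 were not analysed here for the same reason. Prkcz (Entrez gene 18762), which encodes the other atypical protein kinase C, measured 9.57 ± 0.30 in controls and 9.03 ± 0.23 in knockouts (log2 intensity, SD, n = 3), a difference of -0.54 that did not pass (limma adjusted p = 0.394) and was -0.30 under both settings for Y-linked signal described below.

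Knockout crypts had lower levels of alpha-defensins and other Paneth cell genes, with Defa26 9.78-fold lower, and of 3 cytochrome P450 genes and 3 absorptive enterocyte genes. They had higher levels of S100a6 (4.79-fold), of Myl7 and Gsta3, whose signal was above background on only 1 and 2 of the 3 control arrays, and, as a list, of cholesterol synthesis genes (camera adjusted p = 2.35e-07; adjusted p = 0.199 with an estimated correlation). In all, 95 of 7729 genes were called by limma with Benjamini-Hochberg adjustment, 44 higher and 51 lower in the knockout. Knockout replicates 2 and 3 carried signal on a Y-linked probe, described below, while knockout replicate 1 and the controls did not. The grouping thus does not fully separate genotype from a possible difference in sex. For each of the 95 genes the 3 knockout values lay outside the range of the 3 control values. Among all tested probes 16.5% had such groups without overlap, where chance gives 10%. By probe, 135 were called, 53 higher and 82 lower, and 21 of them had no gene symbol. Of the 33 called genes with more than 1 tested probe, 3 had a probe of opposite sign, and in 6 every other probe was called too.

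**Figure D1:**
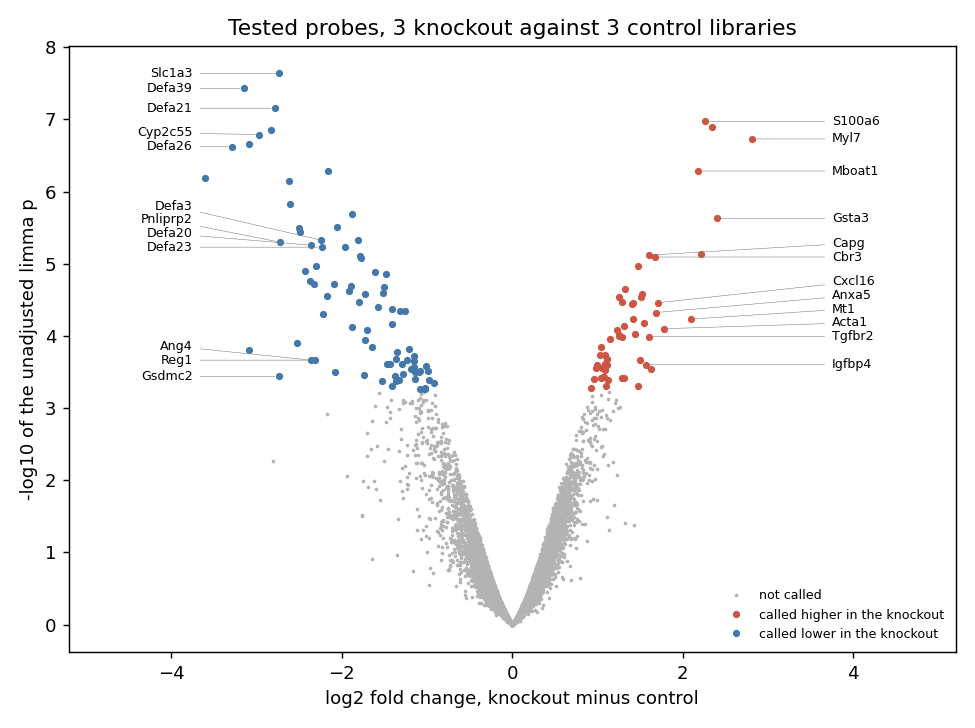
Each point is 1 of 12217 tested probes, with the log2 fold change (knockout minus control, n = 3 each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Colored points are the 135 probes called at an adjusted p under 0.05, and the names are those of the 12 called genes with the largest change on each side; Defa26 lies at -3.29 and Myl7 at 2.81.

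The largest falls among called genes included 6 alpha-defensins, led by Defa26 and Defa39. Outside the defensins, Cyp2c55, a cytochrome P450, was at least 5.45-fold lower in the knockout, and the glutamate transporter gene Slc1a3 was at least 5.45-fold lower. The lipase gene Pnliprp2 was at least 5.32-fold lower. These 3 are lower bounds on the background-corrected scale, since their probes were not detected on any knockout array. Each array of the dimmer group was set to its lowest level of a detected probe or the probe's own, whichever was higher. The bounds carry no error, and without background correction these falls were smaller, as given below. Gsdmc2, a gasdermin, fell by 2.74 ± 0.55 (log2, SE), Ang4, an angiogenin-family antimicrobial ribonuclease, fell by 2.36 ± 0.44, and Reg1, a secreted lectin-like protein, fell by 2.32 ± 0.44. Gsdmc2 was detected on only 1 of the 3 knockout arrays, so its size is uncertain. The limma adjusted p-values of Gsdmc2, Ang4 and Reg1 were 0.0386, 0.0291 and 0.0291. These 3 calls were lost without control replicate 3 or knockout replicate 2, for Gsdmc2 and Ang4 also without knockout replicate 3, for Ang4 and Reg1 also without control replicate 1, and for Gsdmc2 also without knockout replicate 1. Their limma adjusted p then reached 0.123, 0.134 and 0.133.

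The largest rises began with Myl7 (Entrez gene 17898), an atrial myosin light chain, at 2.81 ± 0.25 on the log2 scale (SE, limma adjusted p = 0.000285). It was detected on 1 of the 3 control arrays and Gsta3 on 2, so the sizes of these 2 rises rest partly on control signal at background. Gsta3, a glutathione transferase, rose by 2.40 ± 0.28, S100a6 (Entrez gene 20200), a calcium-binding protein, by 2.26 ± 0.19, and Mboat1, a membrane acyltransferase, by 2.18 ± 0.22. Without background correction the changes of Myl7, Gsta3 and Mboat1 were 1.60, 1.29 and 1.23, still called. Mt1, a metal-binding metallothionein, rose from 13.28 ± 0.78 to 15.37 ± 0.29 (SD, n = 3). Its knockout values, up to 15.60, lay near the highest level of 16.11, so the size of this rise is uncertain. The other named rises were Acta1 (1.78), Cxcl16 (1.71), Anxa5 (1.68), Tgfbr2 (1.61), Capg (1.60) and Igfbp4 (1.56), which include an actin, a chemokine, an annexin and an actin-capping protein. Cbr3, a carbonyl reductase, was not detected on any control array and was at least 2.48-fold higher in the knockout on the background-corrected scale. Without 1 library the limma adjusted p reached 0.0917 for Acta1 (control replicate 1 or knockout replicate 2), 0.0621 for Anxa5 (control replicate 3, knockout replicate 2 or 3) and 0.110 for Tgfbr2 (control replicate 1, knockout replicate 2 or 3). It reached 0.169 for Igfbp4 (knockout replicate 2 or 3) and 0.0514 for Mt1 (knockout replicate 3).

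The gene count changed with single libraries. It was 59 without control replicate 1, 82 without control replicate 2 and 56 without control replicate 3. It was 130 without knockout replicate 1, 30 without knockout replicate 2 and 40 without knockout replicate 3. Part of the falls can come from having fewer arrays. With the knockout reduced to replicate 1, the only knockout library without Y-linked signal, 8 genes were called, and with a term for the 2 libraries that carry it, 14 genes were called. Defa26, Defa39, Defa21, Slc1a3, S100a6 and Mboat1 were called under both of these settings.

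Fold changes depended on background correction, and single calls on the processing. Of 38 called genes followed across the settings, 19 had a log2 fold change over 1.5 times closer to 0 without background correction, and the same number with the authors' value table. Without the correction Defa21 measured -1.64, Defa23 -1.33, Cyp2c55 -1.53, Slc1a3 -1.39, Pnliprp2 -1.41, Acta1 1.02, Igfbp4 1.01, Acaa1b -0.90 and Cbr3 0.73, all still called. Calls were lost there for Gsdmc2 (-1.58), Tgfbr2 (0.85), Anxa5 (0.88), Lss (0.67), Ciart (0.45), Olfm4 (-0.90), Mettl7b (-0.84), Reg1 and Ang4 (limma adjusted p from 0.0534 to 0.215), and for the same 9 with the value table. Without the detection filter 26 of the 38 lost their call (limma adjusted p up to 0.347). Trended and robust eBayes ended the calls of Reg1, Ang4 and Gsdmc2 (up to 0.161). The replicate block ended those of Lyz1, Reg3a, Olfm4 and Ciart (up to 0.0723). The mean of a gene's probes ended those of Capg (0.81), Lss (0.64), Gsdmc2 and Ciart (up to 0.242). The probe with the largest variance ended that of Lyz1 (0.0762), and cyclic loess that of Lss (0.0524). With the knockout reduced to replicate 1 and with the Y-linked term, 32 and 30 of the 38 lost their call, and Mettl7b, Tgfbr2 and Anxa5 moved over 1.5 times closer to 0.

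Paneth cell genes were lower in all 3 knockout libraries. All 6 tested alpha-defensins, the secreted antimicrobial peptides of Paneth cells, were called lower, also when adjusted over the list alone, with a median fall of 5.96-fold. Defa26 (Entrez gene 626708) went from 11.59 ± 0.53 in controls to 8.30 ± 0.46 in knockouts (log2 intensity, SD, n = 3), a 9.78-fold fall, and Defa39 (Entrez gene 382000) from 10.18 ± 0.43 to 7.03 ± 0.19, an 8.89-fold fall. Defa20, the brightest of them, went from 15.38 ± 0.26 to 13.01 ± 0.63. Its control values lay near the highest level of 16.11, so the size of that fall is uncertain. Defa21, Defa3 and Defa23 fell by 2.79, 2.24 and 2.24 on the log2 scale. Alpha-defensins are near-identical in sequence, so a probe of 1 of them can bind RNA of the others.

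Of 10 tested Paneth genes outside the defensins, 4 were called lower. These were Pnliprp2, Ang4, Clps and Lyz1. Clps, which encodes colipase, fell by 1.92 ± 0.28 (log2, SE). Lyz1 (Entrez gene 17110), the lysozyme of Paneth cell granules, went from 13.92 ± 0.15 to 12.90 ± 0.28 (SD, n = 3), a 2.03-fold fall (limma adjusted p = 0.0488), and its call was lost without any of control replicates 1, 2 and 3 and knockout replicates 2 and 3 (up to 0.253). Adjusted over the list alone, 7 were lower and 1 was higher, the phospholipase gene Pla2g2a (1.27), named after its value was seen and detected on 2 of the 3 control arrays. The median log2 fold change of the list was -0.89.

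Joined into a list of 16 genes, the Paneth cell genes had a median log2 fold change of -2.08 (camera p = 6.00e-23; p = 0.0118 with an estimated correlation). The mean level over the 16 genes was 10.11 ± 0.32 in controls and 8.50 ± 0.21 in knockouts (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest this design allows. Called separately, the defensin list had a camera adjusted p of 5.39e-20 and the other Paneth list 2.35e-07; with an estimated correlation both had an adjusted p = 0.199. The list medians of the knockout libraries against the control mean were -1.80, -1.96 and -2.29 for replicates 1, 2 and 3.

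**Figure D2:**
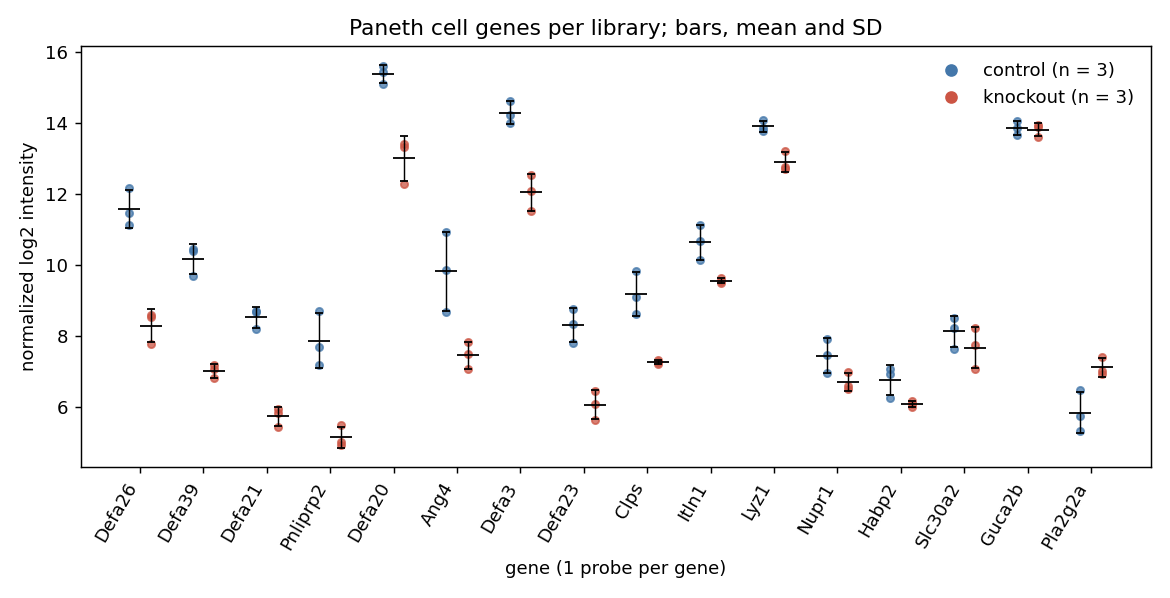
Normalized log2 intensity (vertical axis) of the 16 tested Paneth cell genes (horizontal axis) in 3 control and 3 knockout libraries; points are libraries, bars the mean and SD. Defa26 stands at 11.59 in controls and 8.30 in knockouts, while Guca2b differs by -0.04.

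Goblet cell genes, the other main secretory group, showed no shift as a list. Of 16 tested, 1 was called lower and 0 higher, also when adjusted over the list alone, and the median log2 fold change was -0.01 (camera adjusted p = 0.591). The lower was Klk1, a kallikrein protease (-1.26, limma adjusted p = 0.00950), named after its value was seen. Muc2, the main secreted mucin, measured 12.92 ± 0.20 in controls and 12.93 ± 0.07 in knockouts (SD, n = 3). Of 10 secretory lineage regulators none was called over all genes or the list alone, with a median of 0.20, among them Gfi1, a zinc-finger repressor detected on 2 of the 3 control arrays, at 0.23 (limma adjusted p = 0.794; list camera adjusted p = 0.591). Of 14 enteroendocrine genes none was called, over all genes or the list alone, with a median of -0.16 (camera adjusted p = 0.234). The enteroendocrine medians of knockout replicates 1, 2 and 3 were -0.75, -0.01 and 0.27, and the list was called lower with the knockout reduced to replicate 1 (camera adjusted p = 0.000157), with the Y-linked term (0.000179), without control replicate 2 (0.0124) and without knockout replicate 3 (0.0104).

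Tuft cell genes were lower as a list, with no single gene called over all genes. All 9 tested members had lower means in the knockout, with a median log2 fold change of -0.97 (camera adjusted p = 1.30e-06; adjusted p = 0.380 with an estimated correlation), and 4 passed when adjusted over the list alone. Alox5ap and Ltc4s, both of leukotriene synthesis, measured -1.70 and -1.20 (limma adjusted p = 0.112 and 0.0653), with Alox5ap detected on 1 of the 3 knockout arrays. Without background correction they were -0.84 and -0.57, and the list median was -0.50, as it was with the authors' value table. With the knockout reduced to replicate 1 Alox5ap was -1.05. Alox5ap was called with the replicate block (0.0248), array weights (0.0231) and without control replicate 2 (0.0177), and Ltc4s with cyclic loess (0.0448), array weights (0.0311) and without control replicate 2 (0.0259). The control libraries themselves spread widely, with list medians of 1.09, -0.75 and -0.17 against their mean, and without control replicate 1 the median log2 fold change was -0.33 (camera adjusted p = 0.000195).

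Among 12 intestinal stem cell genes, 1 was called higher and 1 lower, both also when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.583). The higher was Igfbp4, an insulin-like growth factor binding protein. The lower was Olfm4, a marker of crypt base stem cells, which went from 8.26 ± 0.53 to 6.90 ± 0.30 (SD, n = 3; limma adjusted p = 0.0407). The Olfm4 call was lost without control replicate 2 or 3 and without any of the 3 knockout replicates (up to 0.179), and that of Igfbp4 without knockout replicate 2 or 3 (up to 0.169). Of 23 cell cycle genes none was called over all genes or the list alone, with a median of 0.05 (camera adjusted p = 0.389); without control replicate 2 the list was called higher (0.29, 0.0187).

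Absorptive enterocyte genes were lower as a list. Of 23 tested, 3 were called lower, 9 were lower when adjusted over the list alone, and the median log2 fold change was -0.51 (camera adjusted p = 7.53e-10; adjusted p = 0.380 with an estimated correlation). The apolipoprotein genes Apoa4 and Apoc3 fell by 1.61 ± 0.22 and 1.41 ± 0.23, and Lct, which encodes lactase, fell by 1.30 ± 0.25 (log2, SE). The Apoc3 call was lost without control replicate 3 or knockout replicate 2 or 3 (limma adjusted p up to 0.0943), and the Lct call without control replicate 1 or 3 or knockout replicate 2 or 3 (up to 0.138). The list medians of knockout replicates 1, 2 and 3 against the control mean were 0.03, -0.87 and -0.67. The list call was lost with the knockout reduced to replicate 1 (median 0.03, camera adjusted p = 0.315) and with the Y-linked term (0.03, 0.404).

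Of the lists that mark intestinal segments, 7 proximal small intestine genes had a median of -0.84 (camera adjusted p = 6.91e-06; adjusted p = 0.362 with an estimated correlation). Called lower were Slc46a1, the intestinal folate transporter, at -2.06 ± 0.24 (SE), and Lct, which is also on the enterocyte list; 5 were lower adjusted over the list alone. Distal ileum genes were not called as a list (9 genes, median -0.24, camera adjusted p = 0.143). Leaving out 1 library moved this median to between -0.36 and -0.08, and with the knockout reduced to replicate 1 it was 0.13. Fabp6, the ileal bile acid binding protein, measured -2.81 ± 0.82 (limma adjusted p = 0.189) and Slc51b -0.56; Fabp6 was called with array weights (0.0467) and without knockout replicate 1 (-3.86, 0.0168). Both rested much on knockout replicate 3, without which Fabp6 measured -1.64 and Slc51b -0.36 (limma adjusted p = 0.291 and 0.840), and under the settings for Y-linked signal Fabp6 came to -0.75 and -0.73 and Slc51b to -0.06 and -0.05. Adjusted over the list alone, 1 distal gene was lower, Fabp6. The distal list was called lower without control replicate 2 (camera adjusted p = 0.0232) and without knockout replicate 1 (0.0129). Of 5 colon genes 2 were called lower, Mettl7b (-1.28) and Ang4, which is also on the Paneth list, with a median of -0.60 (camera adjusted p = 0.00129; adjusted p = 0.380 with an estimated correlation). Both were lower also adjusted over the list alone. The Mettl7b call was lost without control replicate 1 or 3 or knockout replicate 2 or 3 (limma adjusted p up to 0.217). The colon median was -0.38 without control replicate 2 and -0.98 without control replicate 3. The colon call was lost with the knockout reduced to replicate 1 (camera adjusted p = 0.217) and with the Y-linked term (0.213).

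Antimicrobial and acute response genes of the epithelium fell as a list. Of 11 tested, 9 had lower means and 2 higher ones, the antibacterial lectin genes Reg3b (0.27, near the highest signal on the arrays) and Reg3g (0.51), neither called. Called lower were 3, both over all genes and over the list alone: Gsdmc2, Reg1 and Reg3a, a secreted antibacterial lectin that fell by 1.19 ± 0.23 (log2, SE). The Reg3a call was lost without any of the 3 control replicates and without knockout replicate 2 or 3 (limma adjusted p up to 0.184). The median was -0.63 (camera adjusted p = 0.000618; adjusted p = 0.380 with an estimated correlation), and the call was lost with the Y-linked term (0.0612). The median was -0.40 without control replicate 1, -0.96 without control replicate 2 and -0.27 without knockout replicate 3.

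MHC class II genes, which present antigen, were called as a list only: all 9 had lower means, none was called over all genes, 6 passed over the list alone, and the median was -0.86 (camera adjusted p = 2.30e-06; adjusted p = 0.380 with an estimated correlation). H2-Ab1 measured -1.22 and H2-Eb1 -1.03, which came to -0.69 and -0.61 without knockout replicate 3, and H2-Ab1 to -0.58 and -0.56 and H2-Eb1 to -0.53 in each under the settings for Y-linked signal. Per knockout library the class II medians were -0.35, -0.69 and -1.54, and the call was lost with the Y-linked term (0.140). Without knockout replicate 3 the list median was -0.46 (camera adjusted p = 0.000445). Interferon response genes had a median of -0.30 over 25 genes with none called over all genes or the list alone (camera adjusted p = 0.0109; adjusted p = 0.673 with an estimated correlation). Psmb8 measured -1.13 and Ifi27 -0.90; Psmb8 was called with array weights (limma adjusted p = 0.0401) and without knockout replicate 1 (0.0337), and was -0.39 under both settings for Y-linked signal. This list's call was lost without control replicate 3 (median 0.06, camera adjusted p = 0.997) or knockout replicate 3 (-0.02, 0.413), and its median was 0.04 under both settings for Y-linked signal. Of 9 cytokine and NF-kB target genes 1 was called higher, Cxcl16, also over the list alone, with a median of -0.26 (camera adjusted p = 0.297), and the list was called lower without knockout replicate 1 (-0.39, 0.0365).

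Cholesterol synthesis genes rose as a list. All 13 tested had higher means in the knockout, with a median log2 fold change of 0.72 (camera adjusted p = 2.35e-07; adjusted p = 0.199 with an estimated correlation). Over all genes 1 was called, Lss, the lanosterol synthase, at 1.48 ± 0.31 (SE, limma adjusted p = 0.0462), detected on 1 of the 3 control arrays, and 7 passed over the list alone. One of the 2 tested Lss probes had the opposite sign, and the call was lost without any of control replicates 1 and 3 and knockout replicates 2 and 3 (up to 0.267). The list medians of the knockout libraries were 0.60, 0.78 and 0.61. Without background correction the median log2 fold change was 0.45, as it was with the authors' value table.

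Xenobiotic and glutathione metabolism genes moved both ways. Of 19 tested, 3 were called lower, the cytochrome P450 genes Cyp2c55, Cyp3a25 (-1.89) and Cyp2c65 (-1.88), and 2 higher, the glutathione transferase Gsta3 and the aldo-keto reductase Akr1b8 (at least 2.11-fold, not detected on any control array), the latter named after its value was seen. The Cyp2c65 call was lost without control replicate 1 or knockout replicate 2 (limma adjusted p up to 0.0594). Over the list alone 8 were lower and 2 higher. The median was -0.23 (camera adjusted p = 0.0265; adjusted p = 0.553 with an estimated correlation), and the median was -0.41 without control replicate 1, -0.40 without knockout replicate 1 and -0.47 with array weights. The call was lost and the median came to 0 or above without control replicate 3 (median 0.0048, camera adjusted p = 0.206) or knockout replicate 2 (0.03, 0.159), with the knockout reduced to replicate 1 (0.04, 0.191) and with the Y-linked term (0.04, 0.240). It was also lost with the mean of a gene's probes (-0.18, 0.0587).

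Of 12 PPAR target and ketogenesis genes 1 was called lower over all genes and the list alone, Acaa1b, a peroxisomal thiolase, at -1.57 ± 0.24 (SE). The list median was -0.11 (camera adjusted p = 0.0383; adjusted p = 0.393 with an estimated correlation). The Acaa1b call was lost without knockout replicate 2 or 3 (limma adjusted p up to 0.0673). The list call was lost, with the median near 0, without control replicate 2 (median 0.0022, camera adjusted p = 0.175), without knockout replicate 2 (0.0080, 0.149) and under both settings for Y-linked signal (-0.05 in each, 0.449 and 0.433). It was also lost without control replicate 1 (-0.21, 0.0620) or knockout replicate 3 (-0.09, 0.0515), with the stricter detection filter (0.0644) and with the replicate block (0.0552). Where the call held, the median was -0.37 without control replicate 3, -0.26 without knockout replicate 1, -0.26 without the detection filter and -0.19 with array weights or the mean of a gene's probes.

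Immediate early genes, induced within minutes of stimulation or tissue handling, had a median of 0.40 over 11 genes with none called (camera adjusted p = 0.0103; adjusted p = 0.553 with an estimated correlation), and 3 passed over the list alone, Fos, Atf3 and Dusp1. Dusp1, a MAP kinase phosphatase, measured 1.23 and the stress factor Atf3 0.97; Dusp1 was called with array weights (limma adjusted p = 0.0204) and without knockout replicate 1 (0.0432), and was 0.82 with the authors' value table and 0.37 and 0.38 under the settings for Y-linked signal. Atf3, detected on 2 of the 3 control arrays, was 0.43 without background correction and 0.62 without control replicate 2. The call was lost without control replicate 2 or 3 (camera adjusted p = 0.0534 and 0.0945) and under both settings for Y-linked signal (0.0548 and 0.0612). YAP targets and regenerative epithelium genes had a median of 0.31 over 6 genes with none called (camera adjusted p = 0.0366; adjusted p = 0.380 with an estimated correlation). The median was 0.24 with Il1rn, undetected on control arrays, at its bound; 2 passed over the list alone, Il1rn (at least 1.20-fold higher) and Anxa3 (0.97). Over all genes both were called with array weights and with the mean of a gene's probes, Il1rn also with trended and robust eBayes, and Anxa3 also with the stricter detection filter and the probe with the largest variance (limma adjusted p from 0.0178 to 0.0492). This call was lost without control replicate 1 or 3 (camera adjusted p = 0.0694 and 0.0590), without knockout replicate 2 or 3 (0.0853 and 0.0693), without background correction (median 0.19, 0.0518), with the authors' value table (0.19, 0.0517) and under both settings for Y-linked signal, where the median crossed 0 (-0.04 in each, 0.449 and 0.489). The median was 0.49 without knockout replicate 1 and 0.20 without knockout replicate 3.

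**Figure D3:**
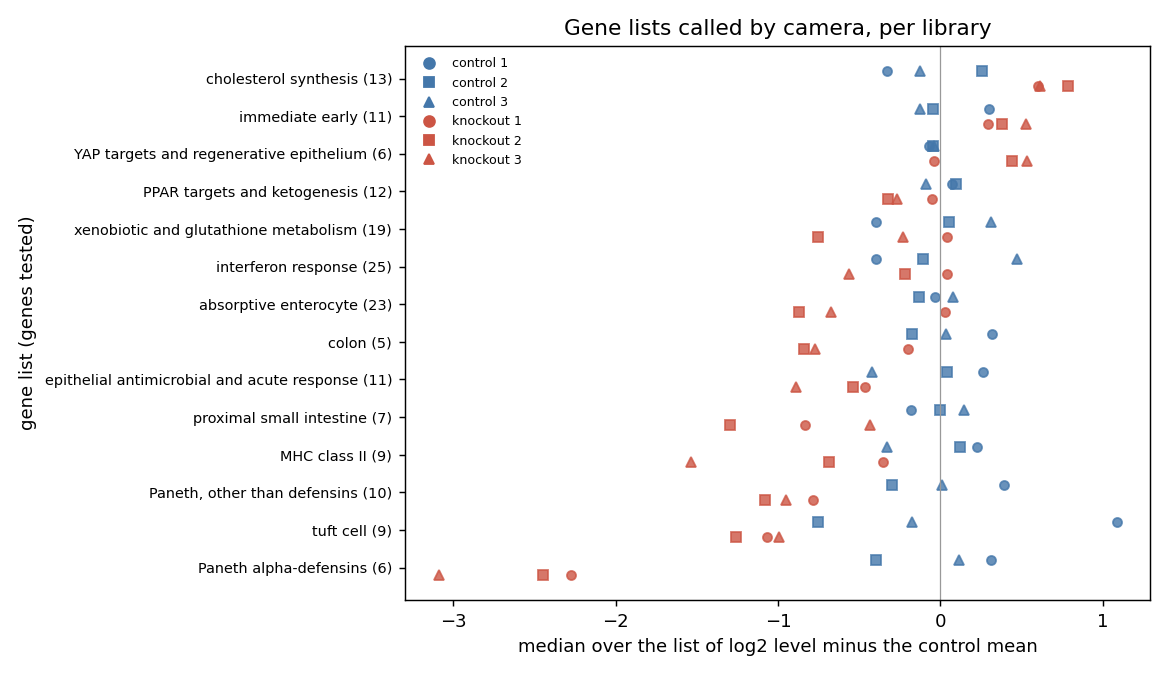
Median over each of the 14 called gene lists (vertical axis, genes tested in parentheses) of the log2 level minus the control mean (horizontal axis) in each of 6 libraries; circles, squares and triangles are replicates 1, 2 and 3. For the absorptive enterocyte list knockout replicate 1 lies at 0.03 and replicates 2 and 3 at -0.87 and -0.67.

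The remaining tested lists were not called. The median log2 fold change was 0.06 for 6 polycomb genes (camera adjusted p = 0.825), -0.04 for 12 atypical protein kinase C and polarity partners (0.517), 0.07 for 21 unfolded protein response genes (0.975) and -0.02 for 18 cell death genes (0.836). It was 0.28 for 6 Wnt targets (0.0988), 0.11 for 7 Notch pathway genes (0.825) and 0.16 for 8 heat shock genes (0.456). No member of these lists was called over all genes except Cd44, a Wnt target and cell adhesion gene, which was higher (1.22, limma adjusted p = 0.0148); adjusted over the list alone, Cd44 was higher and Ddit3, a stress-induced transcription factor, lower. Both were named after their values were seen. For the unfolded protein, Notch and cell death lists the camera direction was opposite to the median. The Wnt list was called higher without knockout replicate 3 (0.37, camera adjusted p = 0.0450) and with the stricter detection filter (0.0390). Of 12 clock genes, Ciart, a clock repressor, was called higher at 1.04 ± 0.19 (SE) and Per1 measured 0.89, with a list median of 0.29 (camera adjusted p = 0.111); over the list alone Ciart and Per1 were higher and Nr1d1 lower. Per1 was 0.44 without background correction and 0.33 and 0.34 under the settings for Y-linked signal. The Ciart call was lost without control replicate 1 or 3 or knockout replicate 2 or 3 (limma adjusted p up to 0.134), and the list was called without control replicate 2 (0.0467).

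Markers of other cell types were measured to see what else the crypt preparations held. T cell and intraepithelial lymphocyte genes had a median of 0.05 over 11 genes (camera adjusted p = 0.701), none called over all genes or the list alone, with Cd3e, a T cell receptor subunit, at 0.41 and at -0.29 and -0.30 under the settings for Y-linked signal. The T cell medians of knockout replicates 1, 2 and 3 were -0.56, 0.28 and 0.43. The list was called higher without control replicate 1 (0.0285) or knockout replicate 1 (0.0175) and with array weights (0.0310), and lower with the knockout reduced to replicate 1 (0.00108) and with the Y-linked term (0.000898). Myeloid genes had a median of 0.13 over 6 genes (camera adjusted p = 0.825), none called over all genes or the list alone, and the myeloid medians of the knockout libraries were -0.59, 0.58 and 0.26. Exocrine pancreas genes had a median of 0.11 over 7, with a lower direction by mean (-0.28) and test (0.265); Clps, called lower over all genes and the list alone, is also on the Paneth list. Lists with under 5 tested genes were not tested as lists and had no member called over all genes or the list alone: medians were 0.24 for 2 B and plasma cell genes, 0.11 for 3 mast cell genes, -0.14 for 3 stromal genes, 0.07 for 3 endothelial genes and -0.68 for 3 erythroid genes. The erythroid medians of the knockout libraries were -1.64, -0.60 and -0.03, and the globin genes Hba-a1 and Hbb-bs measured -0.78 and -0.68, or -0.35 and -0.34 without knockout replicate 1; Hba-a1 was detected on 2 of the 3 knockout arrays. The B cell, mast cell, stromal and endothelial genes with the lowest p measured from -0.55 (Kit, -0.17 without control replicate 1) to 0.41 (Cpa3, detected on 1 control and 2 knockout arrays).

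The libraries also differed in sex-linked signal. A probe of the Y-linked gene Eif2s3y, left out of the test because it was detected on 2 arrays, read 273.9 and 268.7 in knockout replicates 2 and 3 and 82.8 to 112 in the other 4 libraries (raw intensity). A second Eif2s3y probe, the only tested Y-linked probe, differed by -0.05. It was detected on all 6 arrays at raw intensities from 140.3 to 181.8, so the 2 probes of this gene did not show the same pattern. Y-linked signal here refers to the untested probe. All 4 probes of Xist, the X-inactivation RNA, chosen after its values were seen, were detected in the 3 controls and knockout replicate 1 and in neither of the other 2. The lowest limma adjusted p of the Xist probes was 0.144.

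**Figure D4:**
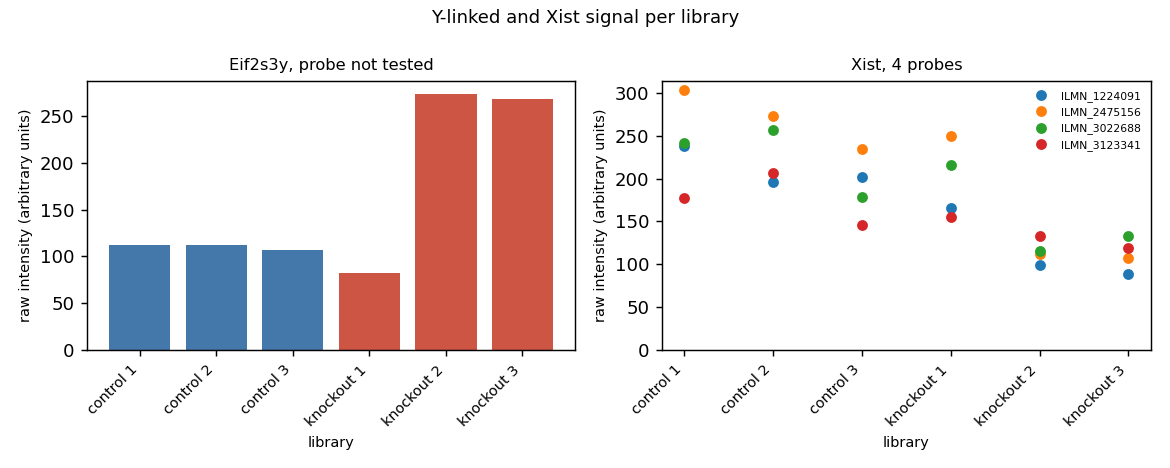
Raw intensity (vertical axes) of the untested Eif2s3y probe (bars) and of 4 Xist probes (points) in each of 6 libraries (horizontal axes). Eif2s3y reads 273.9 and 268.7 in knockout replicates 2 and 3 and at most 112 elsewhere.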

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

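The tests on alpha-defensins and on intestinal segment, and both added settings for Y-linked signal, were chosen after the results were seen. So were the conditions added to the tests on sex, segment, Lyz1 and cross-hybridization.

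Among probes left out of the test, 4 had a detection p under 0.01 on 2 knockout arrays, replicates 2 and 3, and under 0.05 on no control array. How many of the probes left out would do so by chance was not worked out. Eif2s3y, a Y-linked translation factor gene, had a normalized log2 signal 1.74 above that of controls in the knockout mean. For Inf2, Fbxo30 and Peak1 the distance was 0.907, 0.635 and 0.562, with raw intensities of at most 174. Control signal on these probes was not above background, so these distances are no fold changes. With each control at its lowest level of a detected probe or the probe's own, whichever was higher, knockout replicates 2 and 3 were at least 3.82-fold higher for Eif2s3y, 1.67-fold for Inf2, 1.43-fold for Fbxo30 and 1.44-fold for Peak1.

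Sex of the animals is a candidate explanation for part of the shifts, since knockout replicates 2 and 3 carry Y-linked signal and little Xist signal; each list's median in knockout replicate 1, which resembles the controls in this signal, was divided by its median in the other 2. For Paneth cell genes, cholesterol synthesis and proximal small intestine the ratio was 0.832, 0.854 and 0.961, with medians of -1.80, 0.60 and -0.83 in that library. The shift was thus present without Y-linked signal, but 1 library excludes nothing, so sex cannot be told apart from the knockout in these lists. For absorptive enterocyte genes it was -0.0396, so the shift of the list median was in the 2 libraries with Y-linked signal. Sex would give this, and so would any other difference of replicate 1. The genes were split in that replicate, with 11 of 23 on the side of the fall and 10 of them below all 3 controls. Apoa4, Apoc3 and Lct, called with that replicate included, were among these. They read 12.8, 12.3 and 9.6 there, against control means of 14.3, 13.4 and 10.7 (log2 intensity). For tuft cell (1.01) and MHC class II (0.318) it stays open, the first because the control libraries spread by up to 1.63 and the second because the ratio lies between the bounds set.

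The alpha-defensin fall was set against a pair of other readings, and neither was excluded. Cross-hybridization can make 1 defensin's change look like many; the other Paneth genes, with a median of -0.886 (camera adjusted p = 2.35e-07; adjusted p = 0.199 with an estimated correlation), show that the lower values were not limited to defensins but not which defensin each probe read. A lower share of Paneth cells with unchanged content, as the whole cause, would lower Lyz1 as much as the defensins. This holds if the Lyz1 probes read Paneth cells alone. The mean change of the 3 Lyz1 probes lay 1.56 above the defensin median on the log2 scale. The largest standard error of a single Lyz1 probe was 0.25, and the error of the difference was not worked out. Signal from another source would damp the Lyz1 fall, and what those probes read was not tested, so the share of Paneth cells cannot be told apart from their content. A lower defensin content per cell after the deletion remains a hypothesis beside both and beside sex.

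The enterocyte fall was set against the handling of the tissue. Less villus epithelium carried along, lowering every enterocyte gene by about the same factor, is argued against: the log2 fold changes of the 23 genes spread more than their errors give (chi-square 81.3, heterogeneity p = 9.91e-09), and so did the 21 of them detected on all arrays and clear of the highest signal (69.5, p = 2.24e-07), among them Apoa4 at -1.61 and Vil1 at -0.05. An unequal loss, smaller for genes that crypt cells also express, was not tested and stays open. Crypts from a more distal segment would raise distal ileum genes, whose median was -0.241 with a standard error of 0.40. The median lay within that error, which was taken over the 9 genes and not over the samples, so the segment cannot be told apart either. Sex, for which the ratio was -0.0396, stays open.

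The real grouping called 95 genes, and the highest of the other splits of the 6 libraries into 3 and 3 called 0 by limma (at most 685 genes at an unadjusted p under 0.05, against 900 in the real one). The 685 came from the split that put control replicate 1 with knockout replicates 2 and 3, the libraries with Y-linked signal. Every split but the real one mixes the genotypes, so a knockout difference adds to its spread and its count is no chance level. The real split was 1 of 10 with as many genes, and 10 splits are too few for a share under 0.05.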

How the results depend on the processing

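Both settings for Y-linked signal were added after the data were seen. All 95 called genes kept their direction under every setting that tested them, and a stricter filter tested 55 of them. Since none of the 95 had overlapping groups, leaving out libraries could hardly turn a direction. For those settings the kept direction is no separate support. The joined Paneth list kept its direction and call in all 21 alternatives, with medians from -2.29 to -1.37. Its p was not adjusted over the lists, unlike that of the other lists. With an estimated correlation its camera p was 0.0118, while the defensin list and the other Paneth list had a camera adjusted p of 0.199. The exact permutation p of 0.1 is not among these calls. Of the 14 called lists, 13 or 14 were called under the background, normalization, eBayes and probe choices. Quantile, median and loess scaling moved the median of all probes to between -0.02 and 0.02, and median scaling called 37 genes higher and 56 lower.

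Without the detection filter 23 genes (12 higher, 11 lower) and 30 probes were called, with more probes to adjust over. With detection p under 0.01 on all 6 arrays 28 genes were higher and 7 lists lower. Array weights gave 184 genes (72 higher, 112 lower) and 275 probes. An adjusted p under 0.1 gave 144 genes (82 lower) and 215 probes, and an unadjusted p under 0.05 gave 900 genes (468 higher, 432 lower) and 1381 probes. With an estimated correlation 0 lists were called (0 higher, 0 lower; 14 with the preset), and with fry 1 list, the alpha-defensins (0 higher, 1 lower). These tests allow for correlation among a list's genes.

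With the replicate block 73 genes, 110 probes and 13 lists were called; the PPAR list lost its call, and the correlations of same-numbered samples (-0.0852, -0.106 and 0.0379) do not pair them. Leaving out 1 library gave 30 to 130 genes (12 to 49 higher, 18 to 81 lower), 48 to 202 probes, 10 to 17 lists and 1 to 4 lists higher.

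With the knockout reduced to replicate 1, 8 genes (2 higher, 6 lower), 15 probes and 9 lists (1 higher) were called; with 1 library in that group its spread is assumed to be that of the controls. With the Y-linked term, where the contrast rests on replicate 1 as well, 14 genes (3 higher, 11 lower), 23 probes and 7 lists (1 higher, 6 lower) were called. The interferon list turned to medians of 0.0406 and 0.0422. The medians of the xenobiotic list (0.04 in each) and the YAP list (-0.04 in each) crossed 0 as well, and the T cell list turned to -0.55 (camera adjusted p = 0.00108) and -0.56 (0.000898). Fewer samples in the contrast can account for part of the lost calls. Neither this nor the cause of the reversals was tested. Prkci had no value under any setting, and a slide block was not run because no slide was given. Signal near background, as for the Eif2s3y and Xist probes, limits what these arrays show of dim genes.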

Other observations

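These probes and the comparison of knockout replicate 1 with the other libraries were chosen after their values were seen. Of the probes left out of the test, 12 had a detection p under 0.01 on 2 control arrays and under 0.05 on no knockout array. The number that chance would give was not worked out here either. Mptx1, which encodes a mucosal pentraxin, read 437.3 and 412.6 in control replicates 1 and 2, 112.3 in control replicate 3 and 105.1 to 121.4 in the knockouts (raw intensity). Gsdmc3, a gasdermin of the same family as Gsdmc2, read 435.5, 161.2 and 188.7 in controls and 93.2 to 128.1 in knockouts. Pnliprp1, a relative of Pnliprp2, read 153 to 180 in controls and 115.1 to 128.9 in knockouts. These values were not tested.

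Knockout replicate 1 lay between the groups on the first principal component, which held 36.8% of the variance. Its score was 2.17, against -24.5, -18.9 and -17.0 for the controls and 29.4 and 28.8 for knockout replicates 2 and 3. With the probe of each gene chosen over all 6 libraries, 129 genes were called without knockout replicate 1 (130 with it chosen over the other 5). That library lay on the same side of the control mean in 115 of the 129 (a share of 0.892) and beyond all 3 controls in 106 (0.822). Its median change in that direction was 0.93 on the log2 scale, against 1.47 in the other 2 knockout libraries. In 100 simulated data sets in which it was a control, the shares were at most 0.689 and 0.377. The noise there was independent between probes, while genes in these data can move together (estimated correlation 0.83 for the alpha-defensins). Shares from correlated genes can vary more, so these simulated shares set no bound for them.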
